A study of Mus musculus with 8 samples.

How the data were processed

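The samples were hearts of 4 MHC-Plin5 mice and 4 control mice, all male, of a c57/bl background and 12 weeks old, with fasting given in the source name, per the labels. The series text counts 4 mice per group, so each heart was taken as a separate animal. RNA was isolated with a Qiagen kit and labelled with biotin through the Ambion and Affymetrix whole-transcript kits, per the labels' protocols. The authors made the deposited log2 values by RMA (background correction, quantile normalization and probe summary) in Affymetrix Expression Console, per the submitters' processing notes. The version, the summary level and the background settings are not given in the sources used here. The values ran from 2.02 to 14.66 with no centring of genes visible, as log2 RMA values do. The array medians were 6.04, 6.25, 6.03 and 6.03 in control 1 to 4 and 6.00, 6.02, 5.99 and 6.18 in MHC-Plin5 1 to 4, so the medians over all rows were not equal between arrays. Scanner files, scan dates and slide positions were not used here, so the background correction could not be redone and no batch was tested. Precision is limited by the 4 arrays per group.

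The table held 35556 rows (transcript clusters). GEO's annotation of the platform gave exactly 1 gene symbol to 21789 of them, several to 1621 and none to 12146. The gene IDs of 21698 named rows matched the RefSeq table of the assembly GRCm38.p6, and 0 symbols changed through it. For each of the 999 genes with several rows, the row with the highest mean over all 8 hearts was kept, which left 19938 genes. No filter on dim probe sets was applied, since a filter was run as an alternative. Rows with several or no symbols were tested apart and are not named.

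Each gene was tested with lmFit and eBayes of limma 3.58.1 (no intensity trend, not robust) in R 4.3.3, with genotype as the only term, two-sided, and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Differences are MHC-Plin5 minus control on the log2 scale, and a fold is 2 to the power of that difference. For Plin5 and Myh6 an exact two-sided permutation test over the 8 hearts stands beside it. Groups of genes were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The 40 lists, 29 of pathways and 11 of cell types, were written from textbook knowledge before the data were examined, and Plin5 is in none of them. They hold 954 entries, of which 869 were measured. The number of called members is given over all genes tested and adjusted over the list alone. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and plots.

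The genes named in the text follow a rule fixed before the data were examined. It takes Plin5 and Myh6, the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap, up to 4 members with the smallest p of each pathway list with a called member or a called list, and up to 2 members of each cell type list. Predicted genes named Gm, Rik or LOC were counted and not named: 6 of the 415 higher and 12 of the 233 lower genes. For pathway lists the text is shortened to the lists with the most called members, with fewer members named for the others.

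The gene step was tested on simulated data made for this comparison with 19938 genes, where genes changed by 0.5, 1 and 2 on the log2 scale were called in 50.7%, 89.6% and 97% of cases, and 7 of 165 calls were false. Simulated noise was normal with the same SD in both groups. Real SDs could differ, as in Angpt1 with 1.22 in MHC-Plin5 and 0.08 in control hearts. These rates may therefore not hold for genes of unequal spread. In a simulation of the list step, fatty acid oxidation shifted by -0.5 was recovered (camera adjusted p = 2.86e-33), and 0 of 38 lists sharing no gene with it were called. The simulated genes varied independently of each other, while the real oxidation genes had an estimated correlation of 0.616. The simulation therefore does not show how often lists of correlated genes are called falsely. Alternatives fixed in advance were filters at a mean of 5 or 7, a further quantile normalization, median centring, an intensity trend with and without robust variances, array weights, the mean over a gene's rows, every row of the table, the heart number as a block, the first residual component as a covariate, each heart left out, stricter thresholds, Welch's test per gene, the estimated correlation and fry. After the data were seen, a fit without the 2 arrays with the highest medians, a fit with the array median as a covariate and 5 further gene lists were added. The heart number was not taken to pair hearts across the groups.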

Results

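Gene expression was measured on Affymetrix whole-transcript arrays in hearts of 4 male mice carrying MHC-Plin5 and 4 male control mice, all 12 weeks old and labelled as fasted. The MHC-Plin5 mice overexpress Plin5 in cardiomyocytes, the contracting muscle cells of the heart. Plin5 encodes perilipin 5, a coat protein of lipid droplets, the stores of neutral fat inside cells. The comparison asks which transcripts differ between hearts with raised perilipin 5 and control hearts. The deposited log2 values gave 1 level for each of 19938 genes. Array medians over all rows lay between 5.99 and 6.04 in 6 hearts, with 6.25 in control 2 and 6.18 in MHC-Plin5 4. The first principal component held 45.8% of the variance and ran from -24.3 to -13.3 in the control hearts and from -3.99 to 42.5 in the MHC-Plin5 hearts. Pearson correlations between any 2 hearts ranged from 0.974 to 0.995, so no array was a copy of another. The number of arrays, 4 per group, limits the precision of every value.

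Plin5 itself was 11.7-fold higher in the MHC-Plin5 hearts, with log2 levels of 12.39 ± 0.31 (SD, n = 4) against 8.85 ± 0.20 (SD, n = 4) in control hearts. The 4 MHC-Plin5 hearts lay at 12.17, 12.69, 12.63 and 12.08, and the 4 control hearts at 8.92, 8.87, 9.04 and 8.58. The log2 difference was 3.54 (SE 0.16), with a limma adjusted p of 6.9e-07. The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 hearts can give. Myh6, the alpha myosin heavy chain of the adult heart, stood at 13.21 ± 0.23 against 13.39 ± 0.03 (SD, n = 4 each), and its log2 difference of -0.18 (SE 0.12, adjusted p = 0.482) was not called. The probes may not tell the transgenic from the endogenous Plin5 transcript, so the value may be their sum.

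Asns, which makes asparagine, showed the largest rise and was 22.1-fold higher in MHC-Plin5 hearts (log2 difference 4.46, SE 0.16, adjusted p = 2.76e-07). Mthfd2, a mitochondrial enzyme of folate metabolism, was 20.6-fold higher (4.37, SE 0.18, adjusted p = 6.9e-07). Slc7a5, a transporter of large neutral amino acids, was 9.4-fold higher (3.23, SE 0.14), and Slc7a11, a cystine transporter, 8.89-fold higher (3.15, SE 0.31). Next came Ostn, a secreted peptide, with a log2 difference of 2.71 and Maoa, a monoamine oxidase, with 2.61. The transcription factor Myc followed with 2.30, the deubiquitinating enzyme Uchl1 with 2.21 and Chac1, which degrades glutathione, with 2.16. The largest falls were those of Lgi1, a secreted protein, with a log2 difference of -3.32 (SE 0.59), Rpl3l, a striated-muscle form of a ribosomal protein, with -2.70 (SE 0.50). Pla2g5, a secreted phospholipase, had -2.50 (SE 0.51) and Ces1d, a carboxylesterase, -2.50 (SE 0.42). They were followed by Abhd1 with -2.35, the vessel growth factor Angpt1 with -2.19 and the receptor Gpr22 with -1.99. The remaining falls were Fah, the last enzyme of tyrosine breakdown, with -1.85, Hnmt, which inactivates histamine, with -1.84 and the second monoamine oxidase Maob with -1.78. In limma with Benjamini-Hochberg adjustment, 415 of the 19938 genes were higher and 233 lower in MHC-Plin5 hearts. Of these, 280 rose and 174 fell by at least 1.5-fold, and 113 rose and 45 fell by at least 2-fold. The 4 hearts of one group did not overlap the 4 of the other in 641 of the 648 called genes, and in 11.2% of all genes, where chance gives 2.86%. All 648 kept their direction when any single heart was left out. For the 641 without overlap this was fixed in advance, since leaving out 1 heart cannot reverse such groups. The number of called genes moved to 246 without control 1, 317 without control 2, 235 without control 3, 334 without control 4, 233 without MHC-Plin5 2, 344 without MHC-Plin5 3 and 1174 without MHC-Plin5 4. The calls of Maoa and Rpl3l ended without control 1, control 2, control 3 or MHC-Plin5 2, and that of Lgi1 without control 1 or control 3. Uchl1 lost its call without any single control, MHC-Plin5 2 or MHC-Plin5 3, Pla2g5 and Angpt1 without any single control or MHC-Plin5 3, and Gpr22 without any single control or MHC-Plin5 2. The adjusted p of these genes then reached at most 0.116. An intensity trend with robust variances ended the calls of these 7 genes and of Ces1d.

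**Figure D1:**
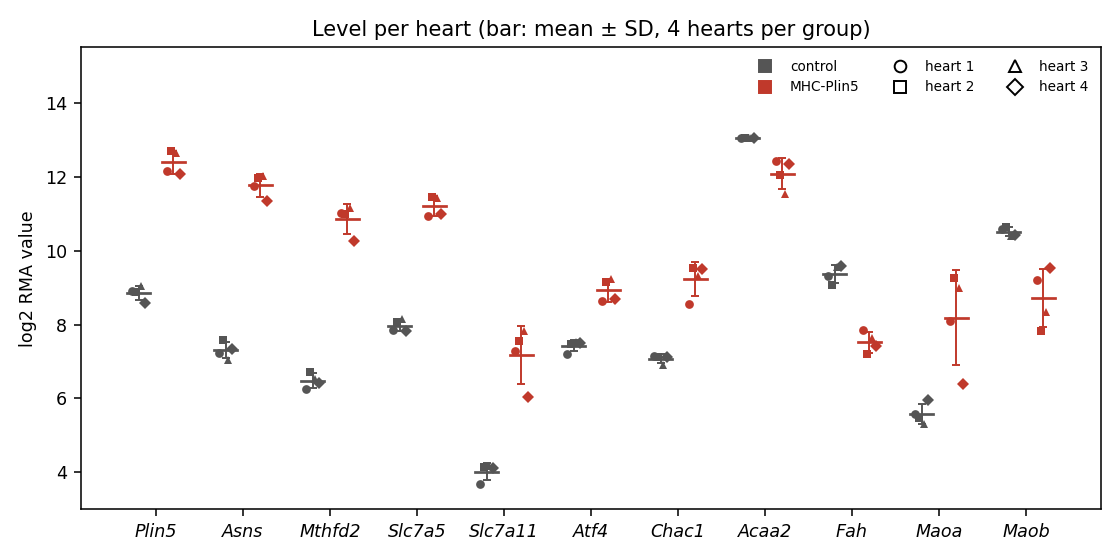
Log2 RMA value of 11 genes (x axis) in each of 4 control hearts (grey) and 4 MHC-Plin5 hearts (red), with a bar at the mean, an error bar of 1 SD and a symbol for each heart number, which does not pair hearts. In Asns the MHC-Plin5 hearts sit between 11.34 and 12.03 and the control hearts between 7.05 and 7.58, and in each of the 11 genes the 2 groups do not overlap.

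The list of endoplasmic reticulum stress and the integrated stress response had the most members called higher over all genes tested. Adjusted over each list alone, the NRF2 targets had more. The integrated stress response is the programme by which cells adjust translation and amino acid supply under stress. The list also holds chaperones of the endoplasmic reticulum, and 0 of these chaperones were called. Of its 31 measured members, 13 were higher and 1 lower (16 and 2 adjusted over the list alone). The 4 members with the smallest p were Asns, Mthfd2, Chac1 (9.23 ± 0.46 against 7.08 ± 0.11, SD, n = 4 each) and Atf4. Atf4, the transcription factor at the centre of the integrated stress response, was 2.83-fold higher, at 8.93 ± 0.31 against 7.43 ± 0.15 (SD, n = 4 each, adjusted p = 0.000521). Vldlr, the lipoprotein receptor that was the 1 lower member, had a log2 difference of -0.63 (SE 0.14). The median over all 31 members was 0.38, and the list stood higher than other genes by camera (adjusted p = 9.85e-11). With an estimated correlation between genes the adjusted p was 0.397, and Vldlr was no longer called without any single control, MHC-Plin5 2 or MHC-Plin5 3.

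Among the antioxidant genes under the transcription factor NRF2, 10 of 34 measured members were higher and 0 lower (21 and 0 adjusted over the list alone). Besides Slc7a11 these included Gss, the glutathione synthetase, with a log2 difference of 0.81 (SE 0.10, adjusted p = 0.00165), Ephx1, an epoxide hydrolase, with 1.19 (SE 0.16), and Srxn1, which repairs peroxiredoxins, with 1.37 (SE 0.18). The NRF2 list had a median of 0.42 and a camera adjusted p of 1.18e-13, with an adjusted p of 0.162 with an estimated correlation. Among 21 genes of the antioxidant enzyme list, which also holds genes of other proteins, 3 were higher and 1 lower (4 and 2 adjusted over the list alone). The metal-binding Mt2 rose by 1.30, the glutathione peroxidases Gpx4 by 0.48 and Gpx8 by 0.57, and the mitochondrial carrier Ucp3 fell by 1.55 on the log2 scale. The list as a whole was not called (adjusted p = 0.121). The number of called NRF2 members was 6 without control 1, 5 without MHC-Plin5 2 and 7 to 13 without any other single heart. The call of Mt2 ended without MHC-Plin5 2, and that of Gpx4 without control 1, control 3, control 4 or MHC-Plin5 2. Gpx8 and Ucp3 lost theirs without control 1, control 2, control 3, MHC-Plin5 2 or MHC-Plin5 3. Without MHC-Plin5 4, 4 of the 21 genes of the antioxidant enzyme list were called higher and 2 lower.

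Cytosolic chaperones and the degradation machinery also had higher members. Hsph1 and Hsp90aa1, chaperones of the heat shock response, were 2.89-fold and 2.95-fold higher (log2 differences 1.53, SE 0.17, and 1.56, SE 0.24). Hspb1 and Dnaja1 had log2 differences of 0.81 and 0.86. A second row of Dnaja1 had 0.57 (limma unadjusted p = 0.00566), and taking the mean over its rows ended the call of Dnaja1. In all, 4 of 16 measured heat shock genes were higher and 0 lower (12 and 0 adjusted over the list alone). The heat shock list had a median of 0.40 and a camera adjusted p of 5.02e-10, with an adjusted p of 0.397 with an estimated correlation. Among 26 genes of autophagy and the lysosome, 4 were higher and 0 lower (5 and 0 adjusted over the list alone). They were the lysosomal proteases Ctsl (0.73, SE 0.09, adjusted p = 0.00181) and Ctsd (0.58, SE 0.10), and the autophagy proteins Gabarapl1 (0.64, SE 0.10) and Sqstm1 (0.76, SE 0.13). These 4 stayed called with any single heart left out. The list median was 0.11 with a camera adjusted p of 0.00304, an adjusted p of 0.397 with an estimated correlation, and 0.0699 after quantile normalization. It was 0.0868 with a filter at a mean of 7, and the median was 0.06 without MHC-Plin5 4. Hspb1 and Dnaja1 lost their calls without any single control, MHC-Plin5 2 or MHC-Plin5 3, which left 2 called heat shock genes.

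Some genes of mitochondrial fatty acid oxidation were called lower. Of 24 measured members, 6 fell and 0 rose (19 and 0 adjusted over the list alone), and all 24 had a log2 difference under 0. Acaa2, which performs the last step of the oxidation cycle, went from 13.05 ± 0.01 to 12.09 ± 0.41 (SD, n = 4 each; log2 difference -0.96, SE 0.17, adjusted p = 0.0136). Ech1 and Decr1, auxiliary enzymes for unsaturated fatty acids, had log2 differences of -0.80 (SE 0.14) and -0.68 (SE 0.13), and Slc25a20, the carnitine carrier of the inner mitochondrial membrane, -0.74 (SE 0.15). The list median was -0.48 and its camera adjusted p 1.65e-13, with an adjusted p of 0.397 with an estimated correlation and of 0.0558 with fry. In these hearts the adipocyte list, which has 8 of its 16 measured genes in other lists, had a median of -0.32 (camera adjusted p = 0.00351, 0.397 as the adjusted p with an estimated correlation). The number of called oxidation genes was 2 without control 1, control 2 or MHC-Plin5 2, 1 without control 3, 4 without MHC-Plin5 3 and 15 without MHC-Plin5 4. Ech1 lost its call without control 3, and Decr1 and Slc25a20 lost theirs without control 1, control 2, control 3 or MHC-Plin5 2.

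**Figure D2:**
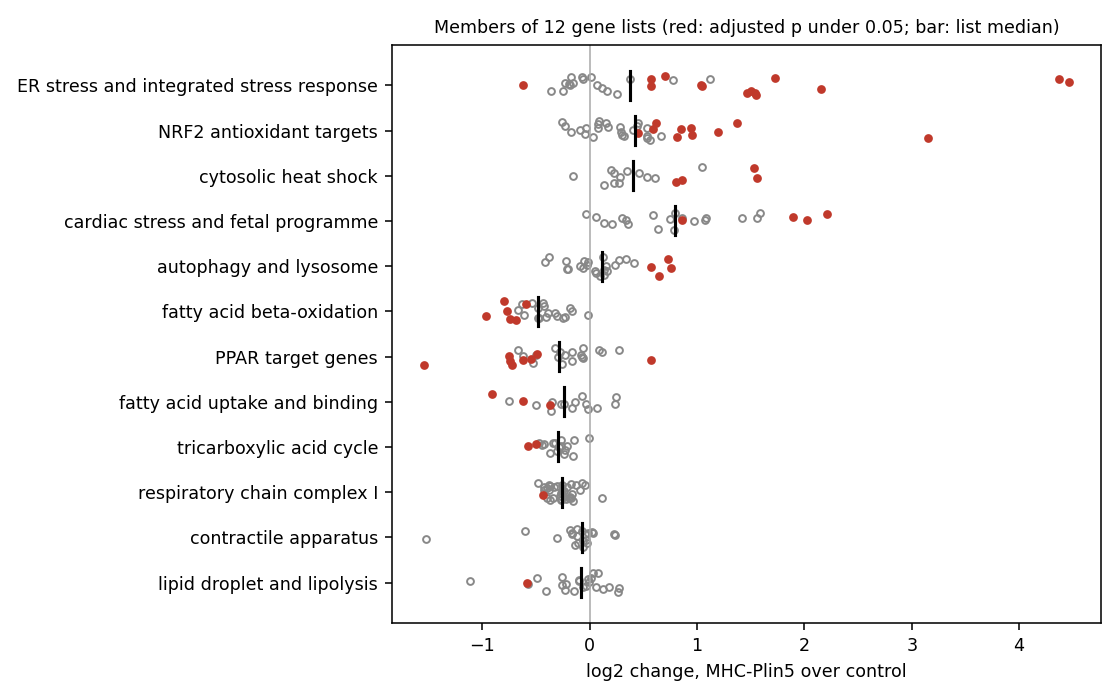
Log2 change of each measured member of 12 gene lists (rows), MHC-Plin5 over control, with members called at an adjusted p under 0.05 in red and a black bar at the list median. The stress and antioxidant lists extend to the right, with Asns at 4.46, and all 24 fatty acid oxidation genes lie left of 0.

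Other lists of lipid handling changed in part. They share members with lists above and with each other, so their counts are not separate results. Slc25a20 is also in the oxidation list, and Vldlr is in the PPAR, uptake and stress lists. Of 26 targets of the fatty acid sensing PPAR receptors, 1 was higher and 7 lower (1 and 11 adjusted over the list alone). Ucp3 was 2.92-fold lower, and Acot1, Slc25a20 and Cyp4b1 had log2 differences of -0.75 (SE 0.15), -0.74 and -0.54 (SE 0.11). Acot1 has a close copy, Acot2, with which its probes may share signal. Of 17 genes of fatty acid uptake and binding, 3 were lower and 0 higher (4 and 0 adjusted over the list alone). They were Acsl6 with -0.91, Vldlr with -0.63 and Dbi with -0.37, while Slc27a1 was not called (-0.75, adjusted p = 0.108). The camera adjusted p was 1.22e-05 for the PPAR targets (median -0.29) and 0.00276 for uptake and binding (median -0.24), with an adjusted p of 0.397 with an estimated correlation for each. Scd4, a fatty acid desaturase, was 3.00-fold lower (log2 difference -1.58, SE 0.16, adjusted p = 0.000508), 1 of 18 genes of fatty acid synthesis (also 1 adjusted over the list alone). That list had a median of -0.15 and a camera adjusted p of 0.0301, with an adjusted p of 0.552 with an estimated correlation. Its call ended without control 4 (median -0.04, adjusted p = 0.51), MHC-Plin5 2 (-0.07, 0.109) or MHC-Plin5 4 (-0.17, 0.0673), and the median was -0.25 without control 1 and -0.28 without MHC-Plin5 3. The lipase Lipe (-0.58, SE 0.13) was the 1 called gene among 24 of the lipid droplet and lipolysis list, and Fitm1 was not called (-1.12, adjusted p = 0.123). Lpcat3, which remodels phospholipids, was lower (-0.73, SE 0.10, adjusted p = 0.00271), the 1 called gene among 25 of triglyceride and phospholipid synthesis. The ceramide synthase Cers6 was higher (0.83, SE 0.18), 1 of 21 genes of ceramide metabolism (2 adjusted over the list alone). These 3 lists were not called (camera adjusted p = 0.231, 0.4 and 0.0644), and neither was cholesterol synthesis, with 0 of 19 genes called and an adjusted p of 0.911. No PPAR target was called without control 1, control 2, control 3 or MHC-Plin5 2, and 1 without MHC-Plin5 3. No uptake gene was called without control 1, control 2, control 3, MHC-Plin5 2 or MHC-Plin5 3, and 1 without control 4. Lipe lost its call with each heart left out except control 4 and MHC-Plin5 4, and Cers6 without control 1, control 2, control 3 or MHC-Plin5 3. Without MHC-Plin5 4, 3 lower genes were called in each of the lipid droplet and the phospholipid synthesis lists and 2 higher in ceramide metabolism, and without MHC-Plin5 1 a gene of fatty acid synthesis was called higher. Ceramide metabolism as a list was called without control 1 (adjusted p = 0.0354) or MHC-Plin5 4 (0.0373).

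Few genes of mitochondrial energy metabolism were called. In the tricarboxylic acid cycle 2 of 18 genes fell and 0 rose (12 and 0 adjusted over the list alone), Sucla2 by 0.58 (SE 0.13) and Fh1 by 0.50 (SE 0.11) on the log2 scale. In complex I of the respiratory chain 1 of 34 genes fell and 0 rose (15 and 0 adjusted over the list alone), Ndufs8 by 0.43 (SE 0.10), and Ndufs1 (-0.43, adjusted p = 0.0657) was not called. Slc2a1, the glucose transporter GLUT1, was 2.46-fold higher (log2 difference 1.30, SE 0.20, adjusted p = 0.00608), the 1 called gene among 25 of glycolysis and glucose uptake (3 higher and 4 lower adjusted over the list alone). That list was not called (adjusted p = 0.4). Camera gave the tricarboxylic acid cycle (median -0.30) an adjusted p of 9.25e-08 and complex I (median -0.26) 2.86e-09. For complexes III to V (median -0.16) it was 0.000228, with 0 of 36 genes called and 1 higher and 2 lower adjusted over the list alone, and its median was -0.09 without MHC-Plin5 3. With an estimated correlation their adjusted p values were 0.4, 0.48 and 0.569. The list of mitochondrial biogenesis and dynamics, with 0 of 23 genes called and a median of -0.10, was not called (adjusted p = 0.0824). It was called after quantile normalization (adjusted p = 0.00622), with a filter at a mean of 7 (0.0345), with the array median as a covariate (0.0342) and without control 2 (0.0129) or MHC-Plin5 1 (0.0219). Sucla2, Fh1 and Ndufs8 each lost the call without any single control, MHC-Plin5 2 or MHC-Plin5 3. Without MHC-Plin5 4 the called lower genes were 5 in the tricarboxylic acid cycle, 6 in complex I, 2 in complexes III to V and 2 in biogenesis and dynamics, and glycolysis had 3 higher and 3 lower. Without MHC-Plin5 1 they were 3, 2, 0 and 1, and glycolysis had 2 higher and 2 lower.

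**Figure D3:**
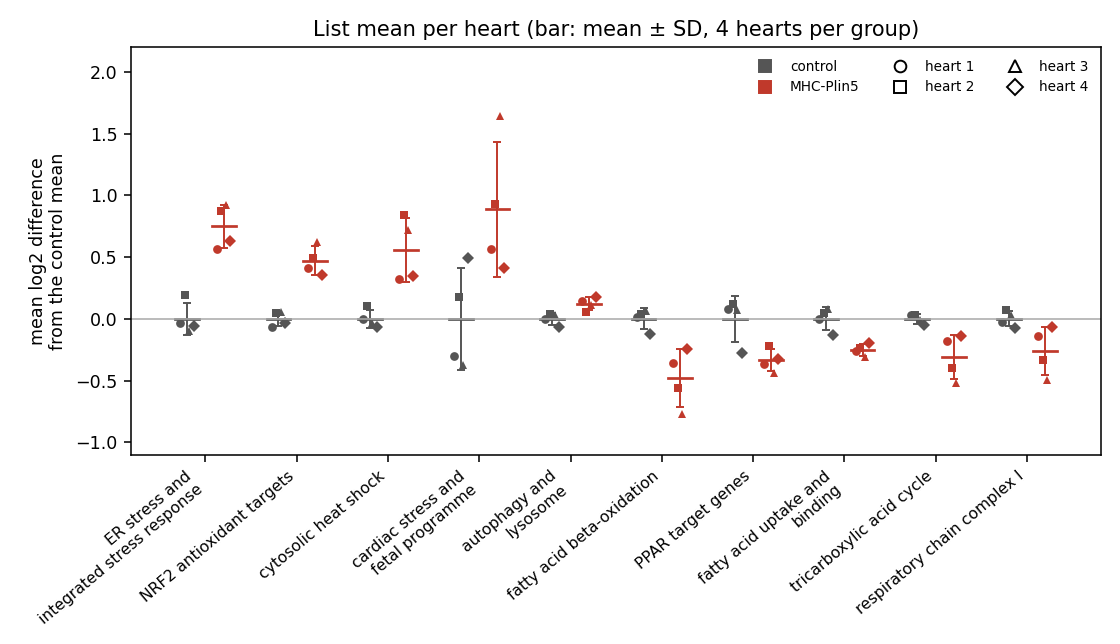
Mean log2 difference from the control mean over the measured members of 10 gene lists (x axis), for each of 4 control hearts (grey) and 4 MHC-Plin5 hearts (red), with a bar at the group mean, an error bar of 1 SD and a symbol for each heart number. For the list of endoplasmic reticulum stress and the integrated stress response the MHC-Plin5 hearts lie between 0.569 and 0.922. For fatty acid oxidation they lie between -0.774 and -0.241.

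Acta1, the skeletal form of actin that is expressed in the fetal heart, was 3.72-fold higher (log2 difference 1.90, SE 0.21, adjusted p = 0.000917). Nmrk2, a kinase of nicotinamide riboside, had a log2 difference of 2.02 (SE 0.45), Uchl1 of 2.21 (SE 0.50) and Ankrd1, a stretch-responsive nuclear protein, of 0.86 (SE 0.17). Of 23 genes of the cardiac stress and fetal programme, 4 were higher and 0 lower (10 and 0 adjusted over the list alone). Nppa, the atrial natriuretic peptide, spread over 12.37 ± 1.02 in control hearts and 13.45 ± 0.56 in MHC-Plin5 hearts (SD, n = 4 each) and was not called (adjusted p = 0.238). It is also in the list of atrial cardiomyocytes, whose mean difference from the control mean was -0.812, 0.339, -0.906 and 1.38 in control 1 to 4. In MHC-Plin5 1 to 4 this was 0.046, -1.024, 1.146 and 0.621. An uneven share of atrial tissue between hearts was not separated from the Nppa values. The cardiac stress list had a median of 0.80 and a camera adjusted p of 1.24e-09, with an adjusted p of 0.397 with an estimated correlation. Among 29 genes of calcium handling and ion channels, the pacemaker channel Hcn4 was lower (-1.34, SE 0.25, adjusted p = 0.0175) as the 1 called gene (5 lower adjusted over the list alone). The list, with a median of -0.17, had a camera adjusted p of 0.00173 and an adjusted p of 0.552 with an estimated correlation. In the contractile apparatus 0 of 21 genes were called, with 0 adjusted over the list alone, a median of -0.08 and a camera adjusted p of 0.109. The list was called after quantile normalization (adjusted p = 0.0226), with a filter at a mean of 7 (0.0385) and without control 2 (0.0298) or MHC-Plin5 1 (0.0393). Its median was -0.04 without MHC-Plin5 3 and -0.14 without MHC-Plin5 4. Called cardiac stress genes numbered 1 without control 1, control 3, control 4, MHC-Plin5 2 or MHC-Plin5 3, 2 without control 2 and 9 without MHC-Plin5 4. Acta1 was called each time. Hcn4 lost its call without control 1, control 2 or control 3. Calcium handling had 2 lower genes without MHC-Plin5 1, 1 higher and 1 lower without MHC-Plin5 2 and 5 lower without MHC-Plin5 4, and the contractile list 1 lower without MHC-Plin5 1 or MHC-Plin5 4.

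Matrix, immune and proliferation lists had few called members. Col8a1, a short-chain collagen, rose by 1.17 (SE 0.25) as the 1 called gene among 33 of the extracellular matrix. Tlr4, a receptor for bacterial lipopolysaccharide, rose by 1.16 (SE 0.22) as the 1 called gene among 28 of inflammation. The same 1 gene was called in each when adjusted over the list alone. Myc was the 1 called gene among 24 immediate early genes (5 higher and 1 lower adjusted over the list alone), and Dusp1 was not called (-0.49, adjusted p = 0.114). No gene was called by limma among 24 of the interferon response (2 higher adjusted over the list alone) or 26 cytosolic ribosomal proteins (0 adjusted over the list alone). Ifit3 stood at 1.07 (adjusted p = 0.06) and Rpl4 at 0.33 (adjusted p = 0.0673). Camera placed all 5 lists higher, with medians of 0.37 for matrix (adjusted p = 1.07e-06), 0.32 for inflammation (5.52e-05), 0.28 for immediate early genes (8.24e-07), 0.15 for the interferon response (0.00407) and 0.21 for ribosomal proteins (1.44e-07). With an estimated correlation the adjusted p values of these 5 lists were 0.505, 0.483, 0.397, 0.604 and 0.397. Beside them, the macrophage and monocyte markers had a median of 0.25 (adjusted p = 0.0024) and the fibroblast markers of 0.27 (adjusted p = 0.00276), with an adjusted p of 0.563 for each with an estimated correlation. Without MHC-Plin5 3 the medians were 0.19 for matrix, 0.16 for inflammation and 0.19 for immediate early genes, and the interferon (0.00, adjusted p = 0.401), macrophage (0.04, 0.0987) and fibroblast (0.16, 0.105) lists were not called. The interferon median was 0.22 without control 2 or MHC-Plin5 2, and the fibroblast median 0.18 without control 1. With a filter at a mean of 7 the calls of the inflammation (adjusted p = 0.0668), interferon (0.109), macrophage (0.105) and fibroblast (0.0862) lists ended. Tlr4 lost its call without any single control, and Col8a1 without any single control or MHC-Plin5 2. In the other direction, 3 matrix genes were called higher without MHC-Plin5 1 or MHC-Plin5 4. Called immediate early genes were 2 higher without control 4, 4 higher without MHC-Plin5 1, and 2 higher and 1 lower without MHC-Plin5 4. Of the interferon genes 1 was higher without MHC-Plin5 1 or MHC-Plin5 3 and 2 without MHC-Plin5 4.

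Of the 3 remaining pathway lists none was called by camera. Hlf, a transcription factor with a daily rhythm, was lower (-0.75, SE 0.12, adjusted p = 0.00644) and Ciart, a repressor of the clock, higher (0.68, SE 0.16) among 17 clock genes (the same 2 adjusted over the list alone; list adjusted p = 0.57). Mt2 was the 1 called gene among 23 of the fasting and glucocorticoid response (4 higher and 1 lower adjusted over the list alone; list adjusted p = 0.16). Of 24 cell cycle genes 0 were called, also adjusted over the list alone (list adjusted p = 0.16, but 0.0287 after quantile normalization). Leaving out any single heart except MHC-Plin5 4 ended the call of Ciart. In the fasting list 0 genes were called without MHC-Plin5 2, and 2 higher and 2 lower without MHC-Plin5 4.

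Few markers of the other cell types a heart sample can hold were called. No member was called by limma among 17 macrophage and monocyte markers (1 higher and 1 lower adjusted over the list alone), 16 fibroblast markers or 16 adipocyte markers (0 adjusted over each list alone). Their members with the smallest p were Cx3cr1 at 0.47 and Timd4 at -0.55, Pdgfra at 0.38 and Dpep1 at 0.41, and Lpl at -0.35 and Ucp1 at -0.29. Casq1, a calcium store protein of skeletal muscle fibres, was lower (-1.58, SE 0.30, adjusted p = 0.0179) as 1 of 17 skeletal muscle markers (also 1 adjusted over the list alone). Kcnj8, a potassium channel of pericytes, was lower (-0.43, SE 0.10, adjusted p = 0.0377) as 1 of 14 smooth muscle and pericyte markers (1 higher and 4 lower adjusted over the list alone). These 2 lists were not called (adjusted p = 0.0562 and 0.121). Skeletal muscle was called without control 1 (adjusted p = 0.038), control 3 (0.0246), MHC-Plin5 2 (0.0187) or MHC-Plin5 4 (0.0406), with a filter at a mean of 5 (0.0491) or 7 (0.0382), after median centring (0.0416) and with the heart number as a block (0.0254). Smooth muscle was called without control 2 (0.0349), MHC-Plin5 1 (0.0451) or MHC-Plin5 3 (0.0226), after quantile normalization (0.0485) and with the array median as a covariate (0.0463). No marker was called among 18 of endothelial cells (Erg at -0.32, list adjusted p = 0.456), 16 of lymphocytes (Cd79a at -0.51, 0.262), 11 of nerve and Schwann cells (Sox10 at -0.33, 0.456). The same held for 14 of atrial cardiomyocytes (Kcnj3 at -1.83, 0.604), 13 of epicardium (Krt18 at 1.57, 0.611) and 7 of erythroid cells and platelets (Ppbp at -0.41, 0.981). The atrial list was called higher without control 4 (adjusted p = 0.00631). Casq1 lost its call without control 1, control 2 or MHC-Plin5 2, and Kcnj8 without any single control, MHC-Plin5 2 or MHC-Plin5 3. Smooth muscle had 2 lower markers called without MHC-Plin5 1 or MHC-Plin5 4, and without MHC-Plin5 4 macrophages had 1 lower and epicardium 1 higher.

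Over all 40 lists, camera with the preset correlation of 0.01 called 12 higher and 9 lower. With an estimated correlation camera called 0 and 4 had an unadjusted p under 0.05, the smallest adjusted p being 0.162, for the NRF2 targets. The fry test, which asks whether the genes of a list move one way without comparing them with other genes, called 4 lists higher and 1 lower. The adjusted p was 0.013 for NRF2 targets and for endoplasmic reticulum stress and the integrated stress response, 0.0308 for heat shock and 0.0296 for autophagy and lysosome. It was 0.0296 for the lower list, fatty acid uptake and binding, and fry gave fatty acid oxidation an adjusted p of 0.0558. The median, mean and test differed in sign for 3 lists that were not called, which were epicardium, cholesterol synthesis, and erythroid cells and platelets.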

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

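Both tests on other splits of the hearts were written before their results were seen. The 8 hearts can be split into 2 groups of 4 in 35 ways. The real split called 648 genes and the highest of the other splits 0, so that 1 of 35 gave as many. That is the smallest share that 35 splits can give. Every other split mixes hearts of both groups, so a real group difference widens the spread within its sides. The result argues against chance for the number of called genes as far as 35 splits can, but does not exclude it. For the number of gene lists called by camera at the preset correlation, 6 of 35 splits gave as many as the real 21, and the highest other split gave 25. Chance cannot be excluded for that count.

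In 19 of 350 tested sets of 4 values (those of a named gene, a list or the array median in 1 group) 1 heart lay far from the other 3, where 17.5 are expected by chance (about 1 in 20). The value given for each is the gap to the nearest heart divided by the range of the group. Control 1 was the lowest control for Slc7a11 (0.886), Atf4 (0.86), Mmp14 (0.86), Cox6a1 (0.931), the ribosomal protein list (0.83) and the circadian clock list (0.83). Control 4 was the lowest control for Rpl3l (0.901), Decr1 (0.839), Hrc (0.858), Lpl (0.878) and the list of PPAR targets (0.887). Control 3 was the lowest control for Chac1 (0.896), and control 2 had the highest array median of its group (0.947), at 6.25 against 6.04 for the nearest. MHC-Plin5 1 was the highest MHC-Plin5 heart for Abhd1 (0.831) and the lowest for Dbi (0.903). MHC-Plin5 3 was the lowest for Rpl38 (0.848) and the highest for the interferon list (0.915), where its mean log2 difference from the control mean was 0.805 and the next heart had 0.09. MHC-Plin5 4 was the lowest for Mthfd2 (0.846) and the highest for the adipocyte list (0.965), at -0.129 against -0.516. No explanation of these values was tested.

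Of the 13767 rows with several gene symbols or none, which enter no comparison above, 48 were called, 32 higher and 16 lower, in a limma fit over all 35556 rows that called 301 rows in all.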

How the results depend on the processing

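The fit without the 2 arrays with the highest medians and the fit with the array median as a covariate were chosen after the data were seen. Plin5 was called under every alternative run on it, and no called named gene or list changed direction under any. Of the other 62 called named genes, 27 stayed called throughout and 35 lost the call under at least 1 alternative, at adjusted p values of up to 0.139. Median centring ended the calls of Hspb1, Dbi, Ndufs8 and Kcnj8, and quantile normalization those of Dnaja1 and Gpx8. Against 415 genes higher and 233 lower, array weights gave 884 and 741, the first residual component as a covariate 842 and 703, the fit over every row, named or not, 220 and 81 (more tests), an adjusted p under 0.01 129 and 40, and Welch's test with Benjamini-Hochberg adjustment 23 and 5. Quantile normalization gave 355 lower genes. A stricter threshold lowers counts by construction, and for the other shifts the cause was not tested. With 1 heart left out (fewer arrays) the counts ranged from 170 to 614 higher and from 56 to 560 lower: 177 and 69, 238 and 79, 170 and 65, and 202 and 132 without control 1 to 4, and 413 and 268, 177 and 56, 236 and 108, and 614 and 560 without MHC-Plin5 1 to 4. Without the 2 arrays with the highest medians they were 435 and 282, and 488 of the then 717 called genes were among the 648.

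Against 12 lists higher and 9 lower, an estimated correlation gave 0 and 0, fry 4 and 1, and a mean of at least 7 left 7 higher, with fewer genes tested. The robust variance setting was run on genes alone. Some lists (direction of the set test) and 2 genes that were not called changed direction, and the cause was not tested. As list medians of the log2 difference, cholesterol synthesis had -0.004307 at a mean of at least 5 and with fry, -0.07874 at a mean of at least 7, 0.02013 after quantile normalization, -0.03483 with array weights, 0.04337 with the array median as a covariate, and -0.07239 (without MHC-Plin5 3) to 0.03402 (without control 2) with 1 heart left out. At a mean of at least 7, the circadian clock had 0.009317, atrial cardiomyocytes 0.4393, epicardium -0.05394 and nerve and Schwann cells 0.03339. After quantile normalization the circadian clock had 0.03304 and erythroid cells 0.01892, and with array weights atrial cardiomyocytes had 0.07943. Erythroid cells had 0.006342 with the residual component, 0.05376 without the 2 arrays, 0.07011 with the array median and -0.1716 (without control 1) to 0.1103 (without control 2) with 1 heart left out. Leaving out 1 heart gave -0.08381 (MHC-Plin5 3) to 0.581 (control 4) for atrial cardiomyocytes, called in the latter (adjusted p = 0.00631), -0.3478 (control 1) to 0.1583 (control 4) for epicardium, and for the genes Gp9 -0.2258 (control 4) to 0.02124 (control 2) and Ppbp -0.8705 (control 1) to 0.06236 (control 3).

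The hearts share only a number: deviations from the group mean of same-numbered hearts correlated at 0.187, 0.0254, -0.107 and -0.0403, and not every heart correlated best with its own number. With the number as a replicate block, 330 genes were higher and 177 lower, and 12 lists higher and 10 lower. With filters at means of 5 and 7 the counts were 456 and 522 higher and 249 and 265 lower, and an effect of signal over background was not separated from that of fewer tests.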

Other observations

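The 5 gene lists that are not among the 40, including the chaperones of the endoplasmic reticulum, the 4 tests on the stress genes and the 2 on the oxidation genes were chosen after the result was seen. The genes named in these paragraphs were chosen after their values were seen. A list of 29 measured genes of the amino acid branch of the ATF4 response, 15 of them in none of the 40 lists, had 23 higher and 1 lower (median log2 difference 1.31, camera adjusted p = 2.2e-40, adjusted p = 0.00338 with an estimated correlation). As the 5 lists were written after the largest rises were known, they are no independent evidence of direction. Their camera p values were adjusted over these 5 lists alone, so they cannot be set beside those of the 40 lists. The ATF4 list holds transporters that rose, Slc6a9 by 1.86 (SE 0.11), Slc7a3 by 1.66 (SE 0.19), Slc1a4 by 1.31 (SE 0.22) and Slc3a2, the partner chain of Slc7a5, by 1.16 (SE 0.12). Of its enzymes Aldh18a1 rose by 2.04 (SE 0.16), Psat1 by 1.54 (SE 0.17) and Phgdh by 1.47 (SE 0.22), while Psph was not called (0.10, adjusted p = 0.798), and Nupr1, a stress-induced nuclear protein, rose by 1.48 (SE 0.12). Each of the 8 risen genes named here stayed called with any single heart left out, and 20 to 23 of the list were then higher, while the 1 lower gene, Vldlr, lost its call without any single control, MHC-Plin5 2 or MHC-Plin5 3.

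Of 18 cytosolic aminoacyl-tRNA synthetases, the enzymes that load amino acids onto tRNA for translation in the cytosol, 12 were higher and 0 lower (median 0.92, camera adjusted p = 7.35e-21, adjusted p = 0.00338 with an estimated correlation). They included Gars at 1.55 (SE 0.11), Sars at 1.39 (SE 0.14) and Yars at 1.33 (SE 0.11), while Kars at 0.05 (adjusted p = 0.836), Qars at -0.12 (0.565) and Wars at 0.20 (0.43) were not called. Of 16 mitochondrial synthetases 0 were higher and 1 lower, Hars2 at -0.43 (adjusted p = 0.0494), with a median of -0.08 and a camera adjusted p of 0.0523. That median was -0.04 without control 3, and -0.12, -0.02, -0.04 and -0.16 without MHC-Plin5 1 to 4 in turn. These counts of synthetases were the same after quantile normalization and after median centring. With each heart left out except MHC-Plin5 4, 9 cytosolic synthetases were called and Hars2 was not (adjusted p from 0.0574 to 0.163), and without MHC-Plin5 4 13 were called. Among 12 mitochondrial chaperones and proteases the protease Lonp1 rose by 0.99 (SE 0.10, adjusted p = 0.000508), and the list median was 0.05 (camera adjusted p = 0.0523), or -0.004275 after quantile normalization, 0.08 without control 1 and 0.02 without control 4. After median centring 2 of them were called higher, and without MHC-Plin5 4 2 higher and 1 lower.

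The rise of the list of endoplasmic reticulum stress and the integrated stress response was weighed against 4 explanations. After a further quantile normalization, 12 of the 13 higher members were called and no other of the 31. The deposited values had already been quantile normalized, and the step moved log2 differences by -0.0578 to 0.0726 (1st and 99th percentile). It could therefore undo only small scaling differences left in the deposited values, and it argues against those alone. Without MHC-Plin5 1 to 4 in turn 12, 10, 12 and 13 members were called higher, which argues against 1 aberrant heart. Of 18 chaperones of the endoplasmic reticulum, 13 of them members of the same stress list, 0 were called higher. Their median was -0.1001, with a bootstrap interval of -0.178 to 0.0137 that resamples the genes, not the hearts. The median was 0.01693 without control 2, -0.16 without control 3, -0.04 without MHC-Plin5 1 and -0.15 without MHC-Plin5 3. These values argue against a folding load that raises chaperones as a class, while Ern1 (0.98) and Atf6 (0.57), sensors of such a load, rose. Atf6 was not called after the further quantile normalization (adjusted p = 0.0523) or without any single control, MHC-Plin5 1 or MHC-Plin5 2 (adjusted p 0.0771 to 0.134). More macrophages or fibroblasts as part of the cause stay open: the median over all 31 members, 0.3771, lay above the 75th percentile of 33 markers of these cells (0.3705) and below the highest, Mfap5 at 0.7675 (0 of 17 and 4 of 16 markers are in other lists, and the most abundant, Lyz2 and Dcn, moved by 0.16 and 0.07). In MHC-Plin5 1 to 4 the mean difference of the stress list was 0.569, 0.878, 0.922 and 0.635. It was -0.023, -0.044, 0.604 and 0.381 for the macrophage markers and -0.134, 0.209, 0.606 and 0.285 for the fibroblast markers. In MHC-Plin5 1 and 2 both marker lists lay within the range of the control hearts, and the stress list above it. That argues against such cells as the whole cause in these hearts. What lies upstream of the rise was not tested, and effects of the insertion site of the transgene stay open.

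The fall of the fatty acid oxidation genes could come from a lower share of cardiomyocytes or from the scaling of arrays. The contractile genes had a median of -0.07535 (bootstrap interval -0.14 to -0.0371) against -0.4772 (-0.612 to -0.381) for the oxidation genes. These intervals resample the genes of a list, not the hearts, so they hold no spread between hearts. The medians were -0.04079 against -0.3836 without MHC-Plin5 3 and -0.1352 against -0.544 without MHC-Plin5 4. In MHC-Plin5 1 to 4 the mean difference of the contractile list was -0.057, -0.148, -0.362 and -0.05, each smaller in size than that of the oxidation list. These values argue against a lower share of cardiomyocytes as the whole cause. After the same further normalization the oxidation list stood at -0.5154, which argues only against small scaling differences left in the deposited values. In MHC-Plin5 1 to 4 the mean difference of the oxidation list was -0.355, -0.557, -0.774 and -0.241, beside -0.023, -0.044, 0.604 and 0.381 for the macrophage markers and -0.134, 0.209, 0.606 and 0.285 for the fibroblast markers. A changed mix of cells as part of the cause stays open, since camera at the preset correlation called both of these marker lists higher (medians 0.25 and 0.27). These calls ended with an estimated correlation (camera adjusted p = 0.563 for each) and without MHC-Plin5 3 (0.0987 and 0.105). A response of cardiomyocytes to the transgene also stays open, and a difference in the time fasted between the groups was not tested.

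Called genes lay next to each other more often than in shuffles of the calls over 19856 placed genes of the assembly GRCm38.p6, with 31 neighbouring pairs against a mean of 21.03, and a share of 0.0205 of 10000 shuffles had as many. Flanking DNA of another strain around the transgene or in the background may add such pairs. The shuffles treated all placed genes alike, whatever their level, so a grouping of expressed genes was not separated from this. A single block dense in called genes is argued against, since the fullest window of 20 neighbouring genes held 5 called genes and a share of 0.765 of 2000 shuffles had as many. The 95th percentile of these shuffles was 6, so a block with few called genes would escape this test. In 17 of the 31 pairs both genes changed the same way, among them Myc and Pvt1, and in others they moved apart, such as Maoa (2.61) and Maob (-1.78), where Maoa lost its call without control 1, 2 or 3 or MHC-Plin5 2 (adjusted p 0.0606, 0.0615, 0.0633 and 0.0518), and Hars (0.56) and Hars2 (-0.43), which both lost their calls with any single heart left out except MHC-Plin5 4 (adjusted p 0.0504 to 0.0847 and 0.0574 to 0.163). Shared or opposed regulation of neighbours stays open, and the site of the transgene was not analysed here.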
